A study of Escherichia coli with 8 samples.

How the data were processed

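Ribosome profiling, which sequences the stretches of messenger RNA that ribosomes shield from nuclease, was applied to 8 cultures of Escherichia coli BW25113 ΔacrB. The labels put them in 4 groups of 2 biological replicates. Tedizolid at 20 µg/mL and delpazolid at 80 µg/mL were each given for 2.5 min at 10 times the minimal inhibitory concentration (MIC), and each drug had its own cultures with 2% DMSO alone. Per the labels, cultures were harvested by filtration, lysates were digested with micrococcal nuclease, and footprints were taken from monosomes. The submitters' processing notes name cutadapt 4.4 for trimming, Bowtie for alignment and FastQC for quality reports. Genes carry locus identifiers of strain BW25113, and the genome build and coordinates were not stated.

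Each drug had a codon table and a gene table, both made by the authors from the drug's 2 libraries and its 2 DMSO libraries. The codon table gave, for each listed codon and library, the authors' CPM, RPKM (CPM per kb of gene) and a pause score. From the values in it, the authors' score was the number of reads at the codon per 1000 reads of its gene in that library, and the authors' log2 column was the log2 ratio of the mean drug score over the mean DMSO score. The gene table held the authors' RPKM per library, a translational efficiency given as the ratio of footprint RPKM to RNA RPKM, the log2 of its drug over DMSO ratio, and the authors' p-value of a test of efficiency with its adjusted p-value. The table's 8 RNA-seq columns were not used. The rule by which genes were kept in each gene table was not stated.

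Depth was computed from the spacing of the CPM values, in which 1 step is 1 read (every value lay within 0.05 of a whole number of steps), and ranged from 17.2 to 29.5 M reads per library. No listed codon had fewer than 6 reads in any library of its table, so codons below that level were not seen. Listed codons held between 83.1% and 90.1% of the reads of a library. The tedizolid tables held 163158 codons in 1790 genes and 1245 genes with RPKM, and those for delpazolid held 143259 codons in 1722 genes and 1094 genes with RPKM. Comparisons between drugs used the 1073 genes and 127111 codons in both sets. Sequencing reads carry no guarantee of being independent molecules, so intervals on shares of sites cover counting error only.

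Gene changes were tested on log2(RPKM + 1) with limma 3.58.1 (lmFit and eBayes with trend, R 4.3.3, with data.table at version 1.17.8), 2 drug against 2 DMSO libraries of the same set, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The difference between drugs was the contrast of the 2 responses, each against its own controls, over all 8 libraries. The 19 gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, for lists with at least 5 measured members, and with fry. Counts of list members are given over all genes tested and adjusted over the list alone.

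For sequence context, each library's log2 pause score (plus 0.1 times the library's median) was averaged over the codons with a given amino acid at a given position. The table gives the residues from position -9 to position 1, which makes 220 features of 20 amino acids, and a wider window that had been planned could not be had. Position 0 is the listed codon, taken here as the codon in the ribosomal P site, though the deposited table does not state the site. Position -1 is then the penultimate residue of the nascent chain and position 1 the next codon. Features were tested with limma without trend and adjusted over the 220. Amino acids were also averaged in 9 residue classes. The strongest sites were the 1000 codons with the highest deposited log2 ratio per drug, and shares among them carry exact Clopper-Pearson 95% confidence intervals.

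Gene lists, residue classes, comparisons, thresholds and the rule for named items were set before the data were examined. Named genes were the 10 largest rises and falls past the threshold with the same sign in both collected pairs, the 3 members of lowest p in each list that passed, acrA and tolC, and the 5 largest differences between drugs in each direction. acrB, which is deleted in the strain, had 0 entries. Named contexts were the 10 largest rises and 5 largest falls per drug and the extremes at positions -2 to 1, and named sites the 10 highest with at most 1 per gene. Other genes given as examples were chosen after their values were seen. Tests of translational efficiency, of single codons and of list differences between drugs were added after the data were seen.

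Per the labels, DMSO cultures were collected with the drug culture of the same number, so the numbers pair the samples. The title of the second delpazolid control names the first delpazolid culture, and the pairing by number was kept. Deviations of same-numbered libraries from their group means correlated across genes with r = -0.035 in the tedizolid set and r = 0.181 in the delpazolid set. Fits with the pair as a block were alternatives, as were other pseudocounts, a filter on low values, rescaling to equal medians, other averages over codons, and leaving out each library. Reads per gene worked out from RPKM, gene length and depth came out whole for 100% of values, but count-model tests, planned in case of deposited counts, were not run on them. On simulated data with made changes, the gene tests found 80.6% and 89.6% of changes of 0.5 (log2) in the tedizolid and delpazolid sets, and the test of the difference found 62.7%. Of the calls on simulated data, 2.60%, 3.03% and 3.37% were false in these tests, and 7.41% and 7.62% in the tests of single codons, above the 5% the threshold stands for. The simulation of codons raised 200 of them by 3 (log2) in a single draw, so its shares do not give the false rate of calls on the data.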

Results

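Footprints were measured in a laboratory strain of Escherichia coli that lacks AcrB, the pump subunit of its main multidrug efflux system, after a short exposure to 1 of 2 oxazolidinones, antibiotics that bind the peptidyl transferase centre of the ribosome. The 8 libraries formed 4 groups of 2: tedizolid, delpazolid, and a DMSO control group collected with each drug. The tedizolid libraries held 29.5 and 29.1 M reads, and their controls 25.4 and 17.2 M. The delpazolid libraries held 21.04 and 18.0 M reads, and their controls 21.01 and 22.2 M. Across genes, which are not independent replicates, log2 RPKM correlated between replicates with r from 0.993 to 0.998. Log2 pause scores of codons correlated between replicates with r from 0.893 to 0.955.

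The first comparison asked which genes gained or lost footprints with tedizolid. The largest rises included yneM (BW25113_4599_yneM) and azuC (BW25113_4663_azuC), which encode small proteins, marA (BW25113_1531_marA), the activator of the multidrug resistance regulon, and corA (BW25113_3816_corA), a magnesium channel. yneM went from 369.8 ± 131 to 3095 ± 29.8 RPKM (SD, n = 2), a log2 change of 3.11 (SE 0.16, adjusted p = 5.04e-10), and marA from 244.5 ± 60.1 to 1403 ± 1.20 RPKM, a change of 2.54 (SE 0.12). azuC rose by 2.82, pyrL, the leader peptide of the aspartate carbamoyltransferase operon, by 2.52, corA by 2.27 and marB by 2.06 on the log2 scale. Rises were 1.96 for yhcN, 1.94 and 1.89 for the purine synthesis genes purF and purM, and 1.83 for yrbN. Coding lengths were only 96, 87, 135 and 81 nucleotides for yneM, azuC, pyrL and yrbN, against 951 for corA and 1518 for purF. Across genes the log2 change was higher for shorter genes (Spearman rho -0.34). A rise of short genes in general was not separated from a response of these 4 genes. The largest falls were those of the small heat shock proteins, ibpB (BW25113_3686_ibpB) from 2189 ± 258 to 209.9 ± 50.8 RPKM, a change of -3.39 (SE 0.13), and ibpA by -2.69. Others fell in cell wall and envelope genes, with murE at -2.59, the porin gene ompF at -2.52 and lpxD at -2.17, in the branched-chain amino acid genes ilvC at -2.21 and ilvB at -2.13, and in rsmJ at -2.16, yhdE at -2.10 and prlC at -2.09. In all, 906 of 1245 genes passed the threshold in limma, 376 up and 530 down, of which 73 rose and 171 fell at least 2-fold. The median change was -0.132, and with each library rescaled to the same median 444 genes rose and 456 fell.

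Genes for the translation and transcription machinery went in both directions with tedizolid. Of the 54 ribosomal protein genes, 44 rose, 1 fell (rpsA, -1.01) and 9 did not pass, and adjusted over the list alone 45 rose and 1 fell. rplM rose from 12208 ± 289.5 to 36064 ± 1103 RPKM, and rpsO and rplY by 1.57 and 1.45 on the log2 scale. The list was up in camera (adjusted p = 2.47e-10), with adjusted p = 0.533 with an estimated correlation. RNA polymerase and sigma factors had 9 of 14 genes up and 2 down (9 and 3 adjusted over the list alone), with rpoH, the heat shock sigma factor, at 1.52, rpoZ, the omega subunit, at 1.39 and the transcript cleavage factor gene greA at 1.33. Its adjusted p was 0.0328, and 0.597 with an estimated correlation. Of 23 aminoacyl-tRNA synthetase genes, 18 fell and 1 rose, the same counts adjusted over the list alone, among them serS at -1.13, pheS at -1.098 and hisS at -1.01. That list was down with adjusted p = 0.0239, and adjusted p = 0.597 with an estimated correlation.

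Lists for biosynthesis, energy metabolism and protein folding were lower with tedizolid in camera at the preset correlation, and none of them passed with an estimated correlation, whose adjusted p is given second. Amino acid biosynthesis genes had 25 of 32 down and 0 up, also adjusted over the list alone (adjusted p = 1.54e-05, then 0.597), with asnA at -1.89, serC at -1.87 and ilvC at -2.21. Of 19 heat shock and protease genes, 17 fell and 2 rose, also adjusted over the list alone (adjusted p = 5.06e-05, then 0.533), and beside ibpA and ibpB the protease gene hslV fell by 2.08 on the log2 scale, while rpoH and clpP rose. Outer membrane and envelope genes had 13 of 18 down and 2 up, also adjusted over the list alone (adjusted p = 0.0239, then 0.533), with bamD at -1.25 and bamA at -1.18, which encode parts of the outer membrane protein assembly machine. Glycolysis had 12 of 14 down and 2 up, the same adjusted over the list alone (adjusted p = 0.0361, then 0.597), with ptsI at -0.74, eno at -0.68 and pgk at -0.66. The tricarboxylic acid cycle had 9 of 11 down and 0 up, also adjusted over the list alone (adjusted p = 0.0443, then 0.533, and 0.0904 with the pair as a block), with aceA at -1.71, sucC at -0.78 and acnB at -0.68. ATP synthase and respiration had 23 of 34 down and 4 up, and 25 and 4 adjusted over the list alone (adjusted p = 0.0361, then 0.597, and 0.112 with the pair as a block), with cyoE at -1.40, nuoF at -1.27 and sdhA at -1.16.

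The efflux and multidrug resistance regulon had 4 of 5 measured members up and 1 down with tedizolid, the same adjusted over the list alone (adjusted p = 0.0361, and 0.533 with an estimated correlation). marA, marB and rob, at 1.08, are regulators or regulon members, acrA, the periplasmic partner of the deleted AcrB, rose from 360.8 ± 73.9 to 657.9 ± 27.0 RPKM (0.88, SE 0.12), and tolC, the outer membrane channel, fell from 790.5 ± 20.98 to 360.1 ± 18.4 RPKM (-1.13, SE 0.086). Leaving out tedizolid replicate 1 ended the calls for ATP synthase (0.135), the synthetases (0.0611), glycolysis (0.122) and the tricarboxylic acid cycle (0.0953), and tedizolid replicate 2 those for the same lists (0.153, 0.123, 0.123 and 0.136). Without DMSO replicate 2 the adjusted p was 0.0511 for RNA polymerase, 0.0548 for outer membrane, 0.0817 for glycolysis and 0.0742 for the tricarboxylic acid cycle, and without DMSO replicate 1 it was 0.0595 for efflux.

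The second comparison asked the same of delpazolid. yneM went from 291.0 ± 83.3 to 3082 ± 703 RPKM, a log2 change of 3.41 (SE 0.24, adjusted p = 2.83e-04), azuC rose by 2.87 and pyrL by 2.78. The small protein gene ypdK rose by 2.58, sugE (BW25113_4148_sugE), which encodes a small multidrug resistance transporter, by 2.55 and blr by 2.16 on the log2 scale. Rises were 2.04 for yejG, 2.01 for corA, 1.85 for yhbE and 1.82 for slyX. Like yneM, azuC and pyrL, ypdK and blr are short, at 72 and 126 nucleotides, while corA and yhbE have 951 and 966. Shorter genes again had higher changes (Spearman rho -0.36 across genes), and changes of single genes were not adjusted for length. ibpA went from 2266 ± 347 to 461.3 ± 85.8 RPKM, a change of -2.30 (SE 0.16). ybhC was at -1.96, prlC at -1.80, the leucine operon leader leuL at -1.73, ompF at -1.71, the phosphate transporter genes pstA and pstB at -1.64 and -1.59, hslV at -1.57, and fkpB and yifL both at -1.55. tolC fell from 770.9 ± 44.5 to 397.4 ± 12.3 RPKM (-0.95, SE 0.084). acrA changed by -0.16 (SE 0.095, adjusted p = 0.182), which did not pass, and rescaling to equal medians turned its sign (0.033). In all, 717 of 1094 genes passed the threshold in limma, 244 up and 473 down, of which 54 rose and 96 fell at least 2-fold. The median change was -0.193, and with each library rescaled to the same median 363 genes rose and 343 fell.

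Of the 54 ribosomal protein genes, 39 rose with delpazolid, 2 fell (rpmD and rpsK, at -0.25 and -0.27) and 13 did not pass, and adjusted over the list alone 39 rose and 3 fell. rplY rose by 1.52, rpsO by 1.501 and rplM by 1.33 on the log2 scale, and the list was up in camera (adjusted p = 1.94e-12, and 0.196 with an estimated correlation). None of the lists that follow passed with an estimated correlation, whose adjusted p is given second. RNA polymerase and sigma factors had 7 of 13 genes up and 1 down, also adjusted over the list alone (adjusted p = 0.00275, then 0.448), with greA at 1.62, rpoH at 1.34 and rpoZ at 1.20. Amino acid biosynthesis genes had 19 of 21 down and 0 up, also adjusted over the list alone (adjusted p = 5.13e-04, then 0.448), with asnB at -1.39, serC at -1.19 and pheA at -1.11. Of 18 heat shock and protease genes, 16 fell and 1, rpoH, rose, also adjusted over the list alone (adjusted p = 0.00275, then 0.448), among them the chaperonin gene groS, from 10390 ± 214.5 to 4735 ± 104 RPKM. Outer membrane and envelope genes had 11 of 18 down and 1 up (12 and 1 adjusted over the list alone, adjusted p = 0.0406, then 0.448), with ompT at -1.13 and ompC at -0.92. The tricarboxylic acid cycle had 9 of 9 down, also adjusted over the list alone (adjusted p = 0.0406, then 0.448), with gltA at -0.75, sucA at -0.74 and acnB at -0.57. Glycolysis had 10 of 14 down and 1 up (11 and 1 adjusted over the list alone, adjusted p = 0.0466, then 0.448), with pgk at -0.78, eno at -0.70 and tpiA at -0.68. Leaving out DMSO replicate 1 ended the calls for glycolysis and the tricarboxylic acid cycle (both 0.0841), and glycolysis also missed the threshold without delpazolid replicate 2 (0.0646) or DMSO replicate 2 (0.0663).

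The third comparison asked where the responses to these structurally related drugs differed, at matched multiples of the MIC and matched exposure. Most changes were shared: of 1073 genes measured in both sets, 217 rose with both drugs (74.1 expected if the calls were independent) and 383 fell with both (202.8 expected), while 7 rose with tedizolid and fell with delpazolid and 2 did the opposite. Across genes the log2 changes correlated with r = 0.883. The responses differed for 127 genes by the limma test of the difference, 53 higher and 74 lower with tedizolid. ribB, a riboflavin synthesis gene, differed by 1.69 (SE 0.14, adjusted p = 1.76e-04), at 1.31 with tedizolid and -0.37 with delpazolid. The purine synthesis genes purE and purC differed by 1.31 and 1.19, and guaB by 0.95. The phage shock gene pspB differed by 1.26 and ilvX by 1.12. Lower with tedizolid were murE (-1.42), wecB of enterobacterial common antigen synthesis (-1.26), the protease gene prc (-1.15), the polyamine transporter gene potB (-1.102) and the twin-arginine translocase gene tatC (-1.07). acrA differed by 1.04 (95% CI 0.65 to 1.43), rob by 0.76 and ompF by -0.81. marA and marB were not among the genes measured with delpazolid and could not be compared. For other genes no difference was detected: the interval for tolC was -0.44 to 0.078, for yneM -1.04 to 0.43, for azuC -0.50 to 0.40, for corA -0.019 to 0.53 and for rpsO -0.17 to 0.30. The plot of gene responses to both drugs shows these genes.

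**Figure D1:**
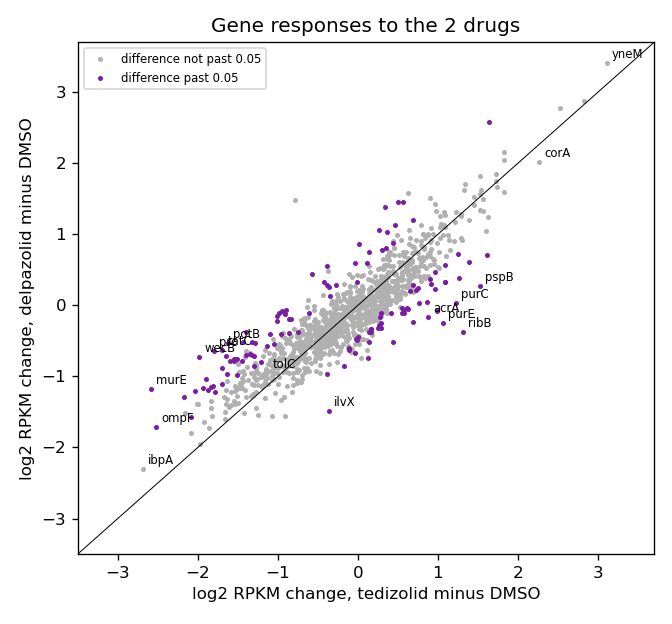
Each point is 1 of 1073 genes, with its log2 RPKM change (drug minus DMSO, means of 2 against 2 libraries) for tedizolid on the x axis and for delpazolid on the y axis. The line marks equal change, and the 127 genes whose responses differed are in purple, with r = 0.883 over all genes.

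None of 17 gene lists passed in the camera test of the difference between drugs, which left 0 lists at the threshold and 2 at an unadjusted p under 0.05. These were membrane protein insertion and secretion (adjusted p = 0.2425), where secG differed by -1.06 and secE by -0.67, and ATP synthase and respiration (adjusted p = 0.2425). The count of 127 genes moved to 201 with the pair as a block, to 27 without tedizolid replicate 1, to 68 without tedizolid replicate 2 and to 195 without delpazolid replicate 2. The calls for potB, ilvX and tatC were lost without tedizolid replicate 1 (adjusted p = 0.0628, 0.108 and 0.108), ilvX also without DMSO replicate 1 or 2 of the delpazolid set (0.0567 and 0.0613), and tatC without delpazolid replicate 1 (0.0508) or DMSO replicate 2 of that set (0.0929).

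Translational efficiency, the ratio of footprints to RNA, was compared for the same genes. With tedizolid it passed the threshold for 630 of 1245 genes in limma, 243 up and 387 down. Among them were ompF, which fell by 1.04 on the log2 scale, ilvC (-1.05) and lpxD (-1.20). Of the largest footprint changes, efficiency did not pass for marA (0.14), marB (-0.13), corA (-0.22), yrbN (0.36), ibpA (0.15), ibpB (-0.24) and ilvB (-0.15). Efficiency rose with footprints for yneM (0.91), azuC (0.33), pyrL (1.29), yhcN (0.36) and purF (0.64). It also fell with them for murE (-0.36), rsmJ (-0.58), yhdE (-0.70) and prlC (-0.54). For purM efficiency fell (-0.71) while footprints rose. The ribosomal protein genes rplM and rpsO had changes of efficiency of 0.81 and 0.67, and over the 54 genes of that list 19 rose and 10 fell. With delpazolid 5 of 1094 genes passed, yneM (2.92), sugE (2.15), ypdK (2.11) and pyrL (1.94) up and rlmH (-1.92) down. Replicates of log2 efficiency differed with an SD of 0.125 and 0.154 in the tedizolid set against 0.536 and 0.661 in the delpazolid set, so the counts of the drugs are not comparable. The delpazolid count was 9 without delpazolid replicate 1, 1 without delpazolid replicate 2, 114 without DMSO replicate 1, 2 without DMSO replicate 2 and 8 with the pair as a block. By the authors' deposited test, 0 genes had an adjusted p under 0.05 in either set, while 468 and 50 had a raw p under 0.05.

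The next comparison asked which amino acids around the ribosome marked codons that gained or lost occupancy with tedizolid. Codons with isoleucine at position -1 gained most, from a mean log2 occupancy of 1.53 ± 0.062 to 2.20 ± 0.044 (SD, n = 2), a change of 0.66 (SE 0.049, adjusted p = 2.08e-33). Histidine (0.61), cysteine (0.61), glutamine (0.56), tyrosine (0.38) and alanine (0.31) at -1 also rose, as did histidine at -3 (0.39), -2 (0.32) and 1 (0.23), tyrosine at -2 (0.33) and glutamate at 0 (0.33). The largest gain was not the highest level: relative to the library mean, isoleucine at -1 went from -0.39 to 0.24. With drug, cysteine (0.63), histidine (0.49) and glutamine (0.47) at -1 lay higher. Glycine at -1 fell from 2.95 ± 0.033 to 2.01 ± 0.054, a change of -0.94 (SE 0.049), glycine at 0 by -0.43 and at -2 by -0.42, and serine by -0.28 at both -4 and 1. In all, 68 of 220 features passed, 50 up and 18 down. Among residue classes, aliphatic residues at -1 rose by 0.17 (SE 0.033, adjusted p = 0.00611), the class of cysteine, asparagine and glutamine at -1 by 0.33 (SE 0.033) and positively charged residues at 0 by 0.26 (SE 0.040). Not all members of a class rose: at -1 leucine changed by -0.11 and asparagine by -0.075, and neither passed. The class of small residues at -1, which includes both alanine and glycine, fell by 0.16 on the log2 scale (SE 0.043). Proline at 0 fell by 0.20 on the log2 scale (SE 0.037), and aromatic residues at -1 changed by 0.091 (SE 0.034, adjusted p = 0.0547).

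With delpazolid, isoleucine at position -1 went from 1.47 ± 0.019 to 2.42 ± 0.0099, a change of 0.95 (SE 0.087, adjusted p = 1.14e-22), and histidine at -1 from 1.78 ± 0.0070 to 2.70 ± 0.081, a change of 0.92. Histidine at -2 (0.60) and -3 (0.49), isoleucine at -2 (0.49), cysteine (0.54) and glutamine (0.48) at -1, and valine at -1 (0.47), 0 (0.46) and 1 (0.49) followed. Relative to the library mean, isoleucine at -1 went from -0.43 to 0.42, while histidine (0.71) and cysteine (0.50) at -1 lay higher with drug. Glycine at -1 fell from 3.07 ± 0.22 to 1.97 ± 0.18, a change of -1.095, with glycine at -2 at -0.53, at 0 at -0.46 and at 1 at -0.30, and serine at 0 at -0.33. In all, 44 of 220 features passed, 35 up and 9 down. Among residue classes, aliphatic residues rose at -1 by 0.44 (SE 0.062), at 0 by 0.28 and at 1 by 0.23, negatively charged residues at 0 by 0.30 and the class of cysteine, asparagine and glutamine at -1 by 0.32. Within these classes leucine changed by 0.099, 0.091 and 0.073 at -1, 0 and 1, methionine at 1 by 0.012 and asparagine at -1 by 0.0064, none of which passed, while valine, which passed at all 3 positions, lost its calls after centring. Small residues at -1 fell by 0.26 on the log2 scale (SE 0.076), a class that holds both glycine, at -1.095, and alanine, which rose by 0.28. Aromatic residues at -1 changed by 0.11 (SE 0.072, adjusted p = 0.278).

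**Figure D2:**
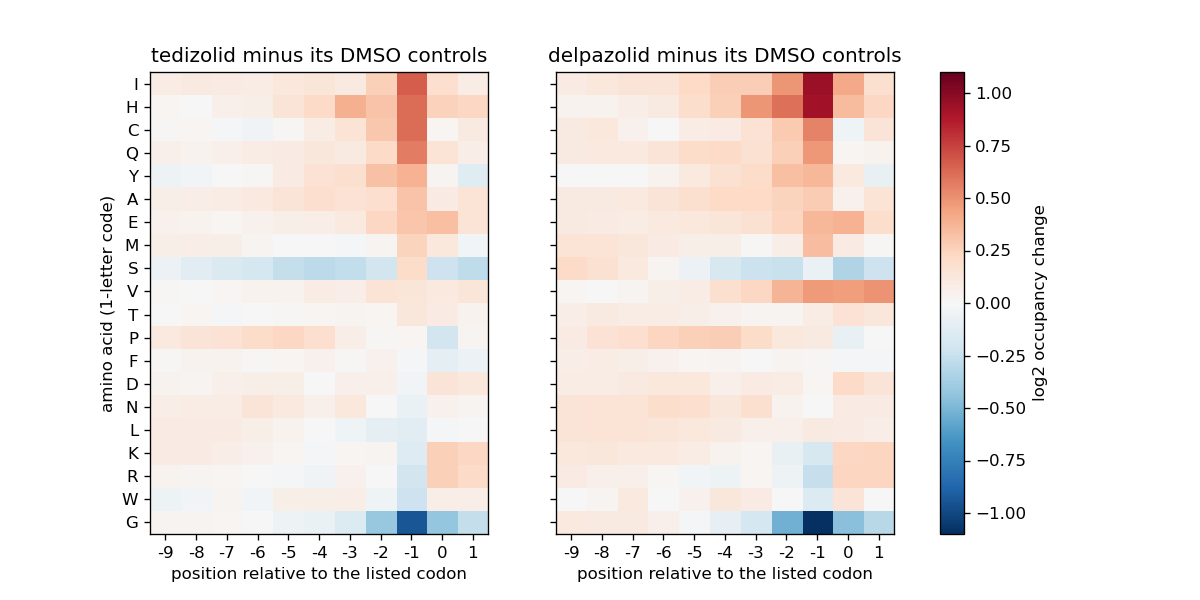
Change in log2 footprint occupancy (drug minus DMSO, means of 2 against 2 libraries) for each amino acid (rows) at positions -9 to 1 from the listed codon (columns), for tedizolid and delpazolid. In both maps position -1 holds the largest changes, up for isoleucine (0.66 and 0.95) and down for glycine (-0.94 and -1.095).

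limma gave all 220 features 1 common variance, and features share codons and library-wide shifts, so these p-values are too small. With each feature's own variance 0 features passed in either drug, though 49 and 26 had an unadjusted p under 0.05. After each library was centred on its mean, 76 features passed with tedizolid, 48 up and 28 down, and 54 with delpazolid, 33 up and 21 down. Glycine and isoleucine at -1 passed there with both drugs, and valine at -1, 0 and 1 with delpazolid did not (adjusted p = 0.123, 0.162 and 0.195). Without delpazolid replicate 1 the change of valine at 1 was 0.31. Serine at 0 with delpazolid rested on DMSO replicate 1, without which its change was 0.035, and was -0.70 without DMSO replicate 2. With tedizolid, glutamate at 0 was 0.22 without DMSO replicate 1 and serine at 1 was -0.17 without DMSO replicate 2. Without delpazolid replicate 2, glycine at -1 (adjusted p = 0.0569), -2 (0.0569), 0 (0.0937) and 1 (0.0874) and glutamine at -1 (0.0569) missed the threshold, and glycine at 1 also did without DMSO replicate 2 (0.139). The tedizolid count was 34 and 33 without tedizolid replicate 1 and 2 and 145 without DMSO replicate 2, and the delpazolid count was 139 and 18 without delpazolid replicate 1 and 2 and 20 without DMSO replicate 1.

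Oxazolidinones such as linezolid are known to arrest ribosomes when alanine is the penultimate residue, so alanine at -1 was compared by itself. It changed by 0.31 with tedizolid (SE 0.049, adjusted p = 4.68e-09) and by 0.28 with delpazolid (SE 0.087, adjusted p = 0.0136), and was higher in both drug libraries than in both controls in each set. An exact two-sided permutation test of the 4 library means gave p = 0.3333 for each drug, the smallest that 2 against 2 libraries allow. It also passed after centring (0.28, adjusted p = 0.00382, and 0.18, adjusted p = 0.0319). Alanine was a residue class by itself, with the same changes. Its pass in the limma test of residue classes (adjusted p = 6.01e-04 and 0.0292) is therefore no further support. With each feature's own variance the adjusted p was 0.120 and 0.368, and with read density (RPM) in place of the pause score the changes were 0.095 and 0.066 and did not pass. The delpazolid call was lost without delpazolid replicate 2 (0.22, adjusted p = 0.120) and without DMSO replicate 1 (0.23, adjusted p = 0.244).

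For the contrast between the drugs, 0 of 220 features passed in limma, and 11 had an unadjusted p under 0.05. Here too the variance was common to all features, with an SE of 0.104, so the intervals below do not carry each feature's own spread. After centring each library on its mean, SEs differed, such as 0.017 for tyrosine at -9 and 0.18 for serine at -9. The lack of calls is therefore not evidence that the drugs acted alike at a given residue. Over the 127111 shared codons, alanine at -1 differed by 0.16 (95% CI -0.045 to 0.36), isoleucine at -1 by -0.16 (-0.37 to 0.044) and histidine at -1 by -0.20 (-0.41 to 0.0029). Valine differed by -0.24 at -1 (-0.45 to -0.037), -0.24 at 0 (-0.44 to -0.031) and -0.23 at 1 (-0.44 to -0.027), each with adjusted p = 0.616. Serine at -1 had the largest difference, 0.38 (SE 0.10, adjusted p = 0.0649), which was 0.20 without DMSO replicate 1 of the tedizolid set and 0.051 and 0.71 without DMSO replicate 1 and 2 of the delpazolid set. Alanine at -1 differed by 0.10 without delpazolid replicate 1. Without delpazolid replicate 1 valine differed by -0.13, -0.10 and -0.061 at -1, 0 and 1, and without delpazolid replicate 2 by -0.35, -0.37 and -0.40, which passed. Serine at -1 passed without DMSO replicate 2 of the delpazolid set. After centring each library on its mean, histidine at -1 alone passed, at -0.28 (adjusted p = 0.00437). The count was 17 without delpazolid replicate 2, 3 without DMSO replicate 2 of the delpazolid set and 1 without DMSO replicate 2 of the tedizolid set.

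**Figure D3:**
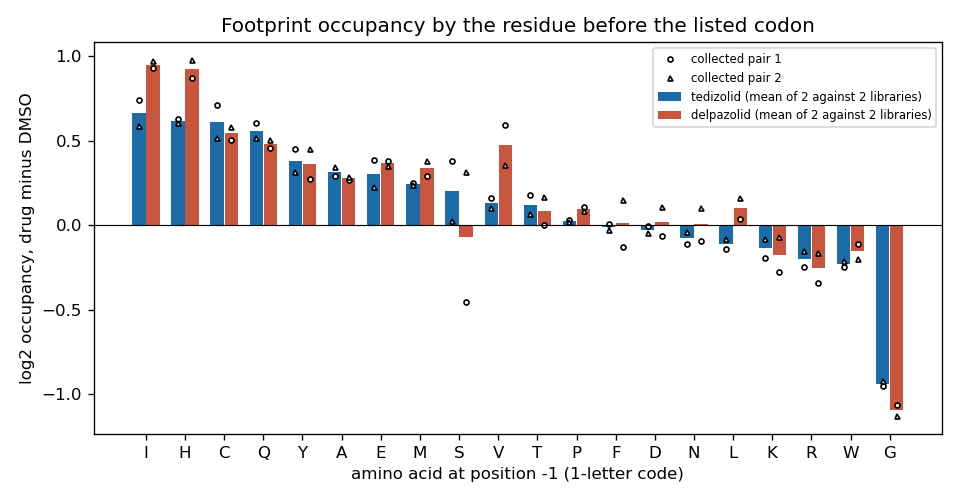
Change in log2 footprint occupancy (drug minus DMSO) by the amino acid at position -1, with bars for the means of 2 against 2 libraries and markers for the 2 collected pairs. Isoleucine was highest and glycine lowest with both drugs, and alanine stood at 0.31 and 0.28.

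Single codons showed which residues marked the strongest sites. Among the 1000 codons with the highest deposited log2 ratio for tedizolid, 23.4% had isoleucine at -1 (95% CI 20.8% to 26.2%) against 5.33% of all listed codons, 7.5% had histidine against 2.21%, 10.7% glutamine against 4.403% and 13.6% alanine (11.5% to 15.9%) against 10.2%. None had glycine there, which allows a share of up to 0.368% (upper 95% limit), against 11.1% of all. Glycine was also rare at 0 (0.5% against 9.28%) and 1 (0.7% against 9.18%). With delpazolid its shares were 0.1%, 1.5% and 1.1% at -1, 0 and 1, against 10.0%, 9.09% and 9.00%. Sites were ranked by the ratio over DMSO, where glycine at -1 lay 1.03 above the library mean in the tedizolid set. A high control level by itself lowers that ratio. For delpazolid, 33.7% had isoleucine at -1 (30.8% to 36.7%) against 6.01%, 12.7% histidine against 2.54%, 7.3% alanine (5.77% to 9.09%) against 10.2%, and 37.7% had valine at position 1 (34.7% to 40.8%) against 8.94%, a share that was 18.6% without delpazolid replicate 1. Valine at 1 held 10.8% of the tedizolid sites (8.94% to 12.9%) against 8.15%. The alanine share was below that of all codons among the 200 strongest tedizolid sites (8.5%). Within the 127111 codons of both sets, the 1000 highest of each drug had 314 in common, where chance gives 7.87. No test across libraries was made of these shares.

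The highest tedizolid sites were lysine 486 of ptsI, whose score went from 0.203 ± 0.0019 to 5.64 ± 1.84 (27.8-fold), histidine 22 of grpE (25.2-fold), tyrosine 36 of bamD (24.8-fold), lysine 64 of typA (24.4-fold), arginine 335 of guaC (24.3-fold), glutamine 30 of tolC (23.3-fold), alanine 316 of dppA (22.2-fold), lysine 16 of glnA (21.1-fold), proline 18 of rhlB (20.9-fold) and valine 312 of ybeZ (20.8-fold). Of these 10, ptsI, bamD, typA and guaC had isoleucine at -1. The highest delpazolid sites were alanine 328 of nuoF, with a score from 0.690 ± 0.088 to 31.8 ± 27.4 (46.2-fold), arginine 26 of nfuA, with a score from 0.670 ± 0.143 to 26.7 ± 17.4 (39.9-fold), isoleucine 337 of ompF (34.2-fold), isoleucine 117 of ibpB (34.1-fold), valine 22 of prlC (33.4-fold), tyrosine 17 of ppa (31.8-fold), glutamate 77 of atpD (31.1-fold), valine 215 of oppC (30.4-fold), valine 99 of bcp (30.3-fold) and threonine 10 of ycdX (30.3-fold). The DMSO libraries had from 6 to 58 reads at these codons. The ranks of nuoF and nfuA rest on delpazolid replicate 1: their log2 changes in limma, 5.201 and 5.16, were 4.18 and 4.44 without it and 6.22 and 5.88 without replicate 2. That of typA, 4.72, was 4.13 and 5.30 without DMSO replicate 1 and 2 of the tedizolid set, and that of bcp, 5.00, was 4.29 and 5.71 without those of the delpazolid set. In limma over single codons, 26140 of 163158 codons rose and 22339 fell with tedizolid, and 22531 of 143259 rose and 17096 fell with delpazolid. Simulated data had 200 codons raised by 3 (log2), and 7.41% and 7.62% of the calls on them were false. That share cannot be carried over to the calls here, which were many more and went in both directions. The total of 48479 for tedizolid was 18518 and 22336 without tedizolid replicate 1 and 2, and the total of 39627 for delpazolid was 14240 and 22653 without delpazolid replicate 1 and 2.

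Occupancy was also followed along genes, as the mean log2 change of the pause score. With tedizolid and delpazolid it was -0.48 and -0.37 at codons 3 to 5, 0.43 and 0.58 at codons 11 to 20, 0.44 and 0.49 at codons 21 to 30, -0.073 and 0.013 past codon 100, and -0.50 and -0.57 at the last 3 listed codons.

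**Figure D4:**
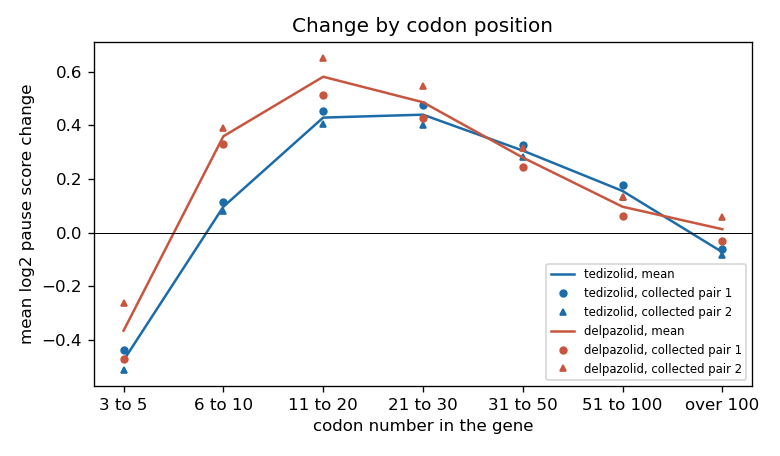
Mean log2 change of the pause score (drug minus DMSO) by codon number for tedizolid and delpazolid, with lines for the means of 2 against 2 libraries and markers for the 2 collected pairs. Codons 11 to 30 lie highest and codons 3 to 5 lowest with both drugs. The last 3 listed codons are not drawn.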

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

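The tests of relative scale, of DMSO levels, of single libraries, of codons that begin with G and of efficiency below were chosen after the result was seen. The results given first are genes whose responses to the 2 drugs differed in the limma test of the difference itself.

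The test passed for 127 of 1073 genes, and 20 genes chosen by the rule for named genes were among them. Higher with tedizolid than with delpazolid, as the difference of log2 responses, were ribB (1.69), purE (1.31), pspB (1.26), purC (1.19), ilvX (1.12), acrA (1.04) and gltA (0.87). Lower with tedizolid were ptsI (-0.37), hslV (-0.51), serC (-0.68), cyoE (-0.70), ompF (-0.81), asnA (-0.86), lpxD (-0.88), ypdK (-0.94), tatC (-1.07), potB (-1.102), prc (-1.15), wecB (-1.26) and murE (-1.42). The drug sets have separate controls, and whether they were sequenced together was not stated, so a difference between sets in how drug libraries were made cannot be ruled out. The count was 27 without tedizolid replicate 1, 68 without tedizolid replicate 2 and 195 without delpazolid replicate 2.

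The fall of glycine at -1 was weighed first. A relative scale, on which reads drawn to drug stalls lower all other codons alike, was argued against, since glycine lay at -0.94 with tedizolid and -1.15 with delpazolid relative to the median of 14 other residues. The read minimum was argued against as well, since the fall was -1.01 and -1.31 among the 10% of genes with the most footprints. In the DMSO libraries glycine at -1 lay 1.03 (tedizolid set) and 1.16 (delpazolid set) above the library mean, against 0.057 and -0.028 with drug. A candidate explanation is therefore that control cultures paused at glycine, as is known for cultures harvested by filtration, and drug-treated cultures did not. The labels give filtration for drug and control cultures alike, so the method of harvest alone cannot set the difference. Whether the pauses in the controls arose at harvest or before it was not tested.

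The rise of valine at -1, 0 and 1 with delpazolid was weighed second. On values not centred on the library mean it was not in 1 library alone, since the lower delpazolid library was 0.31 above the higher DMSO library over the 3 features. It was larger in collected pair 1 (0.59, 0.64 and 0.71 at -1, 0 and 1) than in pair 2 (0.35, 0.29 and 0.27). The share of valine at 1 among the strongest sites went from 37.7% to 18.6% without delpazolid replicate 1. The comparison was not made on centred values, so that replicate as the main source was not excluded. A preference for codons that begin with G was argued against as the whole cause, since alanine, aspartate and glutamate at 0 and 1 rose by 0.19 on average and valine by 0.48. Without codons that hold isoleucine, histidine or cysteine at -1 the rise of valine was 0.35, so that these neighbours as a part of it and a response to valine itself cannot be told apart. After centring each library on its mean the 3 features did not pass (0.37, 0.36 and 0.40, adjusted p = 0.123, 0.162 and 0.195), and no biological explanation was tested.

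The rise of ribosomal protein genes was weighed last. Short genes gained footprints, but coding length was argued against as the whole cause, since a median rise of 0.33 of 0.41 with tedizolid and of 0.46 of 0.51 with delpazolid was left beyond a fit on length over the other genes. With tedizolid the median change of translational efficiency was 0.066, so more messenger RNA may account for most of the median rise. Single genes differed: efficiency rose for 19 of the 54 and fell for 10, and it changed by 0.81 for rplM, 0.67 for rpsO and 0.86 for rplY. With delpazolid the median change of efficiency was 0.44 (quartiles 0.14 and 0.63), close to the median rise of 0.51. Efficiencies of single genes in that set differed between replicates with an SD of up to 0.661, and 0 of the 54 passed. How far the median itself varied between replicates was not computed, so more messenger RNA and more footprints per message were not told apart. The test of the difference between drugs was not made for efficiency.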

How the results depend on the processing

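Tests of efficiency, of single codons and of list differences, and the alternatives of centring, unpooled variances, 20 reads or more, RPM in place of the score and leaving out a library for the strongest sites, were chosen after the data were seen. Where a count or call below changed, the cause was not tested. Where a group had 1 library left, it was assumed to vary like the other groups. The planned count-model alternatives were not run, though reads per gene can be worked out from the RPKM.

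Of 882 values of named genes under alternatives, 874 kept their direction and side of the threshold, 7 lost their call, and acrA with delpazolid turned to 0.033 after rescaling to equal medians. Of 564 for named contexts, 506 kept both, 47 lost and 10 gained a call, and serine at 0 with delpazolid ranged from -0.70 to 0.035 with 1 library left out (0.035 without DMSO replicate 1). All 100 for named codons kept both. Most named genes and contexts and all named codons were picked for large changes in these data. Their calls were therefore likely to be kept, and these shares do not describe calls in general. For gene lists 178 of 216 did, 36 lost and 2 gained a call. With the pair as a block 201 genes differed between drugs and 8 changed efficiency with delpazolid, and among list calls ATP synthase and the tricarboxylic acid cycle with tedizolid were lost and cold shock with delpazolid was gained (adjusted p = 0.0460). The block changed no other call of a named gene, list, context or codon, and calls of unnamed genes were not compared. For named genes with tedizolid this could hardly have come out otherwise. For yneM, limma with the block gave an adjusted p of 5.14e-214, against 5.04e-10 without it. Kept calls there are thus no evidence that the pairing does not matter.

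With an estimated correlation 0 lists passed in camera for either drug (0 and 1 at an unadjusted p under 0.05). By fry, which tests each list by itself, every list passing in camera at the preset correlation passed too, with the stringent response (tedizolid 0.0185, delpazolid 0.00465) and, for delpazolid, synthetases (0.0102), nucleotide biosynthesis (0.0272), leader peptides (0.00950) and oxidative stress (0.0114) besides. Context counts for tedizolid (68) were 44 with each gene weighted equally, 44 with the larger pseudocount, 0 with unpooled variances, 136 with 20 reads or more and 177 with RPM. For delpazolid (44) they were 81 with the plain mean and 0 with unpooled variances. Between drugs 1 feature passed without gene ends, with the plain mean, in genes of above-median density, and when centred. Alanine at -1 did not pass with unpooled variances (0.31 and 0.28) or RPM (0.095 and 0.066). Isoleucine's share of the strongest sites was 32.0%, 18.1% and 27.6% (tedizolid) and 39.5%, 25.1% and 36.6% (delpazolid) for 200 sites, 5000 sites and the top of both pairs, and 34.2% for delpazolid in genes of above-median density.

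Leaving out 1 library gave 698 to 943 genes for tedizolid, 666 to 686 for delpazolid, and 27 to 195 between drugs (27 and 68 without tedizolid replicate 1 and 2, 195 without delpazolid replicate 2). Efficiency gave 526 to 643 and 1 to 114 genes (delpazolid: 9 and 1 without its replicate 1 and 2, 114 and 2 without DMSO replicate 1 and 2). Lists were 6 to 9 (6 without tedizolid replicate 2 or DMSO replicate 2), 5 to 7, and 0 to 1 between drugs (1 without delpazolid replicate 2). Contexts were 33 to 145 for tedizolid (34 and 33 without its replicate 1 and 2, 145 without DMSO replicate 2), 18 to 139 for delpazolid (139 and 18 without its replicate 1 and 2, 20 without DMSO replicate 1) and 0 to 17 between drugs (17 without delpazolid replicate 2, 3 and 1 without DMSO replicate 2 of the delpazolid and tedizolid set). Alanine at -1 was 0.29 to 0.34 and 0.22 to 0.33, not passing for delpazolid without its replicate 2 (0.22) or DMSO replicate 1 (0.23). Isoleucine's share was 20.7% to 24.2% and 31.6% to 33.6%. Codons were 18518 to 62641 (18518 and 22336 without tedizolid replicate 1 and 2) and 14240 to 42322 (14240 and 22653 without delpazolid replicate 1 and 2). Depth limits the codon tables, which list no codon with fewer than 6 reads in a library.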

Other observations

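The plan for the tests in this part preceded their results, except that the residue pairs, the serine values and the genes named as examples were chosen after their values were seen. Lists that missed the threshold had members that changed. Most genes did so, 906 of 1245 with tedizolid and 717 of 1094 with delpazolid, so changed members alone do not set a list apart. With tedizolid, 7 of 10 cold shock genes rose and 3 fell (cspE -1.51), and 3 of 6 SOS genes rose and 1 fell (lexA 1.04). Regulatory leader peptides had 2 of 12 up and 6 down (ivbL -1.99, thrL -1.66), ribosome rescue, assembly and hibernation 6 of 13 up and 3 down (obgE 1.45, hflX -1.32), the stringent response 2 of 6 up and 1 down (rsd 1.29), and translation factors 5 of 13 up and 3 down. Membrane insertion and secretion had 5 of 18 up and 9 down (lspA -1.65, secA -1.29). Nucleotide biosynthesis had 5 of 18 up and 8 down, and oxidative stress 3 of 11 up and 3 down (trxC 1.68). Adjusted over the list alone, these counts were the same. For nucleotide biosynthesis and oxidative stress camera gave the direction up while the median changes were -0.055 and -0.077 and the means 0.13 and -0.019. Without tedizolid replicate 1 the leader peptides passed (adjusted p = 0.0247).

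With delpazolid, 6 of 10 cold shock genes rose and 2 fell (cspA 1.58, cspD 1.42, cspE -1.18), with adjusted p = 0.0650, and 5 of 12 rescue, assembly and hibernation genes rose and 2 fell (obgE 1.41, hflX -1.26). Aminoacyl-tRNA synthetases had 15 of 23 down and 1 up, nucleotide biosynthesis 7 of 14 down and 0 up, translation factors 5 of 13 up and 3 down, the stringent response 3 of 6 up and 2 down, and leader peptides 2 of 8 up (mgtL 1.51) and 5 down. ATP synthase and respiration had 13 of 34 down and 4 up (11 and 4 adjusted over the list alone), and oxidative stress 4 of 10 down and 1 up (3 and 1 adjusted over the list alone, katG -1.02). Membrane insertion had 5 of 17 up (secG 1.39, secE 1.13) and 6 down, and camera gave up for it with a median of -0.11 and a mean of 0.0043. The other counts were the same adjusted over the list alone. Efflux and SOS had 3 and 4 measured members, under the minimum of 5. Those of efflux were acrA, tolC and rob, so marA and marB were not measured with delpazolid.

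The hypothesis that drug adds footprints in the first 20 codons was tested by the excess of codons 3 to 20 over those past 100, which was 0.28 to 0.41 over the 4 collected pairs. The values the hypothesis needs were there, but the gain was not confined to these codons. Codons 3 to 20 rose by 0.22 with tedizolid and 0.40 with delpazolid, codons 21 to 30 by 0.44 and 0.49 and codons 31 to 50 by 0.31 and 0.28, while codons 3 to 5 went down.

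Among pairs of residues, picked for their large changes, with histidine at -1 and valine at 0 the change was 1.24 with tedizolid and 1.77 with delpazolid, with tyrosine at -2 and isoleucine at -1 it was 1.22 and 1.62, and with glycine at -1 and serine at 0 it was -1.71 and -1.78. Serine at 0 lay at 2.62 in DMSO replicate 1 and 1.89 in DMSO replicate 2 of the delpazolid set, against 1.86 and 1.99 with drug. The hypothesis that the next residue sets the size of the change at alanine -1 was tested by its range over the 20 next residues, which was 0.69 with tedizolid and 0.87 with delpazolid. With both drugs codons with alanine at -1 and glycine at 1 were lowest (-0.021 and -0.17). Residues at 1 also mark changes by themselves (glycine at 1 fell with delpazolid by 0.30 on the log2 scale), so the table does not tell a joint effect of alanine and its neighbour from the neighbour's own.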
